A study of Drosophila melanogaster with 2 samples.

How the data were processed

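The data were peak lists from ChIP-seq of Crc-eGFP in whole Drosophila melanogaster embryos, 2 biological replicates of 1 group, with replicate numbers taken from the labels. Chromatin was sonicated to fragments of 200 to 800 bp and precipitated with an antibody against GFP, per the labels. For each of 2 genome builds, dm3 and dm6, there were 4 lists: candidate peaks of each replicate, candidate peaks of both replicates pooled, and the optimal peaks that passed the irreproducible discovery rate filter. The candidate lists were made against a control file, per the deposited file listings; that control was not analysed here. The aligner, the peak caller, their versions and the read depth are not given in the sources used here.

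Each peak carries a signal value that the authors' peak caller assigned, with no stated normalization, so it was used to rank, describe and compare peaks within a list, and medians of the dm3 and dm6 lists are given as description with no test. Each peak also carries −log10 of a q value, as the deposited narrowPeak format defines it; many peaks share its highest value, 1577 of the 2420 optimal dm6 peaks among them, and it served only to break ties. The p-value column of the deposited files is not filled. Because the caller's signal may depend on library depth, signals of the 2 replicates were compared by rank, with a Pearson correlation of log2 signals as an alternative. The pooled call means that optimal peaks are not separate measurements of each replicate, so each replicate's own candidate list was used to compare them. The dm6 replicate lists hold exactly 30000 regions each, which looks like a limit on their number, so their weak ends are truncated. The optimal dm6 peaks were exactly the strongest pooled candidates by signal, so a comparison of optimal with failed candidates is a comparison of strong with weak peaks.

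Coordinates are those of the files in dm6, 1-based, and dm6 is Release 6 of the genome. The genome sequence was the RefSeq copy of Release 6 and the genes were those of the Ensembl annotation BDGP6.54, release 115. No coordinates were moved between builds. Summits were the authors' summit positions. A promoter summit lay within 500 bp of an annotated start of a protein-coding gene, and other summits were assigned by priority to 5' UTR, 3' UTR, coding exon, other exon, intron or intergenic DNA. Sequence elements and 7-mers, with reverse complements merged, were scored as present or absent within 100 bp of the summit and in 1 flanking window centred 1 kb to a side drawn with a fixed seed. Of the symbols in the gene lists, written at the same time as the tests, 7 were renamed in the annotation and found by locus tag, and 2 genes (Cp110 and Cp190) were taken out of the eggshell list because their symbols fit its name pattern but they are not eggshell genes.

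Tests were fixed before the data were examined: one-sided permutation over 1000 circular shifts for the replicate overlap, Fisher's exact test for shares of peaks or genes, exact McNemar tests for summits against flanks, exact binomial tests for chromosome arms, and a permutation test with 100000 resamples for the median signal. Tests were two-sided unless stated otherwise, and Benjamini-Hochberg adjustment ran over the family named with each result at a threshold of 0.05. Shares carry Wilson 95% intervals, which cover counting error only. Genes were named by a rule fixed in advance: those nearest, within 1 kb, to the 25 strongest optimal peaks; crc; up to 4 bound genes of each list with the strongest peaks and up to 4 unbound genes in list order; and the 3 strongest peaks of a described class. Irbp18, Thor, scyl, BEAF-32, RpL14 and RpL28 are named beyond that rule, chosen after their values were seen, as was the comparison of transposable elements.

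Alternatives covered the distance limits, the number of peaks, the stronger 1210 optimal peaks, other backgrounds, 6-mers and 8-mers, the dm3 lists, and leaving out each replicate in turn. The 2420 strongest candidates of the replicate that was kept then stood in for the optimal list and its other candidates for the failed ones, except for the signal of peaks with a CARE, where its own signal at the optimal peaks was used. Matching paired each optimal peak with a failed candidate of the same promoter status and a GC content within 2 percentage points. This matching, the CARE with 1 mismatch allowed and the 300 strongest peaks were added after the data were seen. The replicate overlap, chromosome arm, CARE, 7-mer and gene list tests were tested on simulated data. With bound genes drawn at random from the 6352 genes with a candidate, a list passed in 0.5% of 200 simulations; a list of 80 genes with the odds of binding raised by a factor of 4 passed in 100%, and a list of 20 such genes in 44%, so that the short lists had little power. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.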

Results

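Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map where the transcription factor Crc binds the fly genome. Crc, encoded by cryptocephal (crc), is the Drosophila counterpart of ATF4, a basic leucine zipper protein that carries the integrated stress response and induces genes of amino acid supply and protein folding. The flies carried an extra exon coding for enhanced green fluorescent protein (eGFP), placed in an intron of crc by a MiMIC transposon insertion, so that the endogenous gene made a Crc-eGFP fusion that an antibody against GFP could pull down. Whole embryos of both sexes, collected 0 to 24 h after laying, gave 1 group of 2 biological replicates, and no library from embryos without the tag was analysed here. The comparisons are therefore between the replicates, between peaks that passed the authors' reproducibility filter and candidates that did not, and between peak summits and neighbouring DNA. With 2 replicates of 1 group, the p-values below describe peaks or genes as units within this pair of libraries, and do not measure variation between conditions.

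The authors' lists on the dm6 genome build held 30000 candidate regions for each replicate, 24369 for the pooled reads, and 2420 optimal peaks that passed the irreproducible discovery rate (IDR) filter, which compares peak ranks between replicates to set how many peaks are kept. The optimal peaks covered 0.905 Mb and were 400 bp wide at the median. Their signal, the authors' own score for each peak, ran from 63.98 to 1273.8 with a median of 96.9. All 2420 were the strongest pooled candidates, so the 21949 that failed were the weaker ones by the same score. The number of reads per library is not given in the sources used here, so the read depth behind each peak is unknown.

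The strongest peak of the pooled data lay 40 bp from the start of Ugalt (FBgn0024994), which encodes a UDP-galactose transporter, at X:2703699-2704071 in dm6. Its signal was 1273.8, and it ranked 2 in both replicates, with signals of 516.3 and 761.7. Next came an intronic peak inside ush at 2L:480907-481288 with a signal of 1205.6, and a promoter peak of CG14100 (FBgn0036889) at 3L:19590445-19590797 with 1189.5. Further promoter peaks among the strongest lay at px, a gene of wing vein patterning (947.7), at ph-p, a Polycomb group gene (861.5), at mRpL41, a mitochondrial ribosomal protein gene (833.9), at Chro, which encodes a chromodomain protein (793.5), and at PNPase, an RNA-degrading enzyme gene (792.6). Of the 25 strongest peaks, 16 had a promoter summit, 6 an intronic one, 2 an intergenic one and 1 lay in another exon.

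The same 25 peaks, chosen by their pooled signal, which favours a high rank in both libraries, ranked no lower than 34 among the candidates of replicate 1 and no lower than 32 in replicate 2. Lk6, which encodes a kinase of the translation factor eIF4E, had an intronic peak 967 bp from a start, with a signal of 300.3 in replicate 1 and 492.2 in replicate 2. The promoter peak of larp, a La-related RNA-binding protein gene, had 251.2 and 420.8, and that of GstE13, a glutathione S-transferase gene, had 245.3 and 307.7. Among the 2420 strongest candidates of replicate 1, 1604 had a summit within 100 bp of 1 of the 2420 strongest of replicate 2, a share of 66.3% (Wilson 95% interval 64.4 to 68.1). Shifting the replicate 2 summits around each chromosome 1000 times matched 0.369% on average and 0.785% at most, a one-sided permutation p of 0.001, the smallest that these shifts can give. Shifted summits lose their place at promoters, so signal that both libraries share for any reason would pass. The p therefore does not show that the shared summits are Crc binding. Across the 2289 optimal peaks with a candidate in each replicate, the signals had a Spearman rho of 0.676 (bootstrap 95% interval 0.649 to 0.701). This correlation is across peaks, which are not independent replicates, and it covers only peaks chosen by their pooled signal and found in both libraries, so it does not measure agreement over all candidates.

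**Figure D1:**
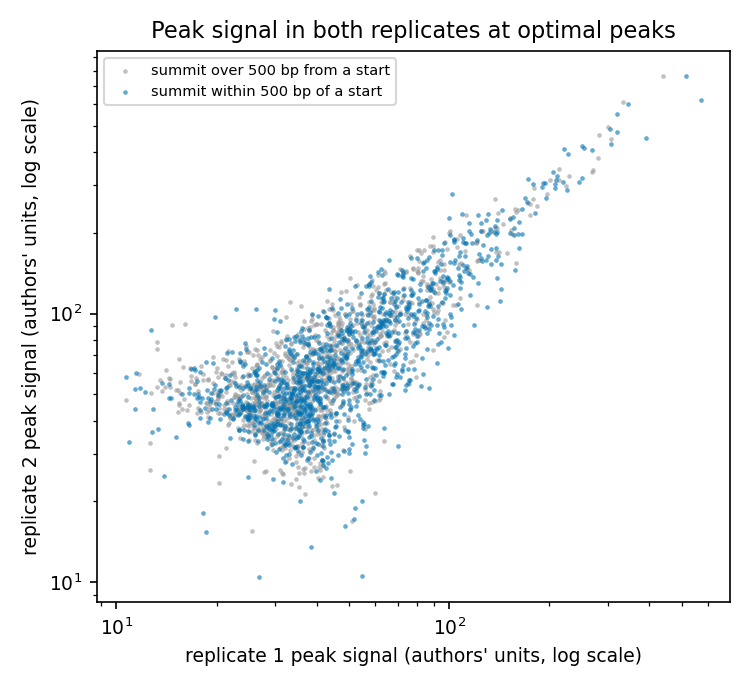
Peak signal of replicate 1 (horizontal axis) and replicate 2 (vertical axis), in the authors' units on log scales, for each of the 2289 optimal peaks found in both; blue points have a summit within 500 bp of a start of a protein-coding gene and grey points do not. The signals rose together, with a Spearman rho of 0.676, and the scatter was wider among weak peaks.

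The crc gene itself (FBgn0000370, 2L:21310866-21319527, forward strand) had no optimal peak, either within the gene or within 5 kb of it. Its strongest candidate, at 2L:21311008-21311407 with the summit 342 bp from a start, had a pooled signal of 49.4 and ranked 3723, below the lowest optimal signal of 63.98. In replicate 1 it had a signal of 40.1 and ranked 1224, whereas replicate 2 had no candidate summit within 100 bp. The gene held 2 further candidates, an intronic one of 19.0 and one in the 3' UTR of 21.5.

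**Figure D2:**
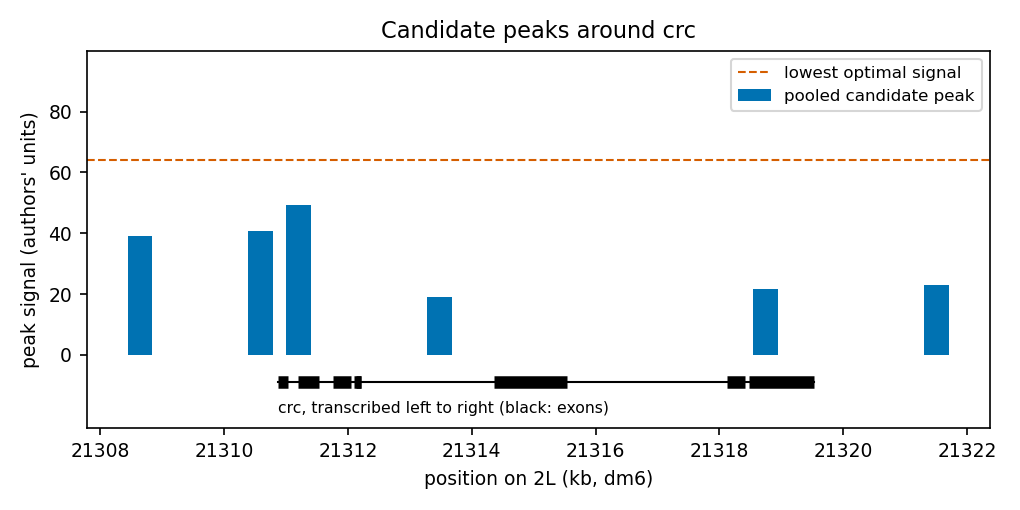
Pooled candidate peaks around crc on 2L in dm6: bar position and width give the peak, bar height its signal in the authors' units, and black boxes the annotated exons. Every candidate drawn lay below the dashed line at 63.98, the lowest signal of an optimal peak.

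Promoters took up the largest share of the optimal peaks. Of the 2420 summits, 1224 (50.6%, Wilson 95% interval 48.6 to 52.6) lay within 500 bp of an annotated start of a protein-coding gene, against 5562 of 21949 failed candidates (25.3%). The odds ratio was 3.02 (Fisher's exact test, two-sided, p = 5.77e-138, adjusted 4.04e-137 over 7 locations), and 8.11 when all bases of the genome replaced the failed candidates. Coding exons were nearly free of optimal peaks: 5 summits (0.207%), the strongest in otp with a signal of 311.9, against 9.28% of the failed candidates (odds ratio 0.0202, exact p = 1.13e-87, adjusted 3.94e-87). Summits in 3' UTRs fell from 3.98% of the failed candidates to 0.868% of the optimal ones, with by (231.7) and Cals (221.9) the strongest. Introns held 843 optimal summits, 34.8% against 40.5%, and intergenic DNA 270, 11.2% against 17.8%, both lower by exact tests (adjusted p = 7.12e-08 and 1.24e-17). The strongest intergenic peak, at 2R:13035182-13035494, had a signal of 744.2 and lay 11925 bp from the nearest start, that of CG13323. The median distance to a start was 486.5 bp for optimal and 1904 bp for failed summits.

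**Figure D3:**
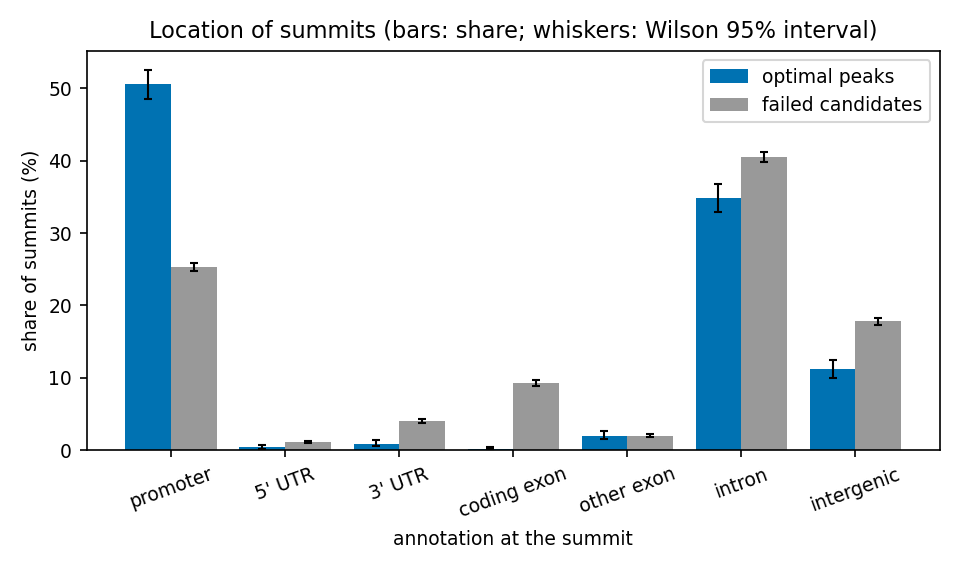
Share of summits by annotation, in percent, for the 2420 optimal peaks (blue) and the 21949 failed candidates (grey), with Wilson 95% intervals as whiskers. The promoter bar stands at 50.6% for optimal peaks and at 25.3% for failed candidates, and the coding exon bar at 0.207% and 9.28%.

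By chromosome arm, X carried 460 peaks where its share of protein-coding starts gave 411.2, a ratio of 1.12, and 2R carried 420 where 494.7 were due, a ratio of 0.849. These were the arms past the threshold (exact binomial tests, two-sided, p = 0.00934 and 1.40e-04, adjusted over 7 arms 0.0327 and 9.79e-04). Chromosome 4 held 9 peaks against 17.8 (adjusted exact p = 0.0741), led by a 3' UTR peak in Cals, and the ratios of 2L, 3L and 3R were 1.00, 1.08 and 1.00. The lists held no peak on Y, where 2.89 were due. Both calls were lost in the 1210 strongest peaks, where the ratios were 1.11 on X (adjusted exact p = 0.322) and 0.849 on 2R (0.0523). On X the call was also lost without replicate 2, with a ratio of 1.07 (adjusted exact p = 0.241), and on 2R when arm length replaced starts as the reference, with 0.944 (0.278).

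Genes of the cytosolic ribosome were bound more often than other genes with a candidate. A gene counted as bound when an optimal summit lay within 500 bp of a start: 1605 of the 6352 genes with a candidate there were, 25.3%, out of 13968 protein-coding genes in all. Of 86 cytosolic ribosomal protein genes, 83 had a candidate and 53 were bound, 63.9% of those with a candidate against 24.8% of other genes (odds ratio 5.37, 95% interval 3.35 to 8.74; Fisher's exact test, two-sided, p = 9.68e-14, adjusted 2.52e-12 over 26 lists). RpS27 (361.5), RpL7 (305.4), RpL32 (286.5) and RpL23A (279.6) had the strongest peaks, while RpL10 (26.1), RpL10Ab (53.7) and RpL12 (48.4) had candidates that failed and RpL10Aa had none. Genes of the mitochondrial ribosome did not pass, with 11 of 59 bound (odds ratio 0.676, adjusted exact p = 0.585), although mRpL41, mRpS23 (672.2) and mRpS10 (496.7) were among the strongest peaks. The cytosolic ribosome was the only list of the 26 past the adjusted threshold, and 3 lists had an unadjusted exact p under 0.05. Its odds ratio was 4.81 without replicate 1, with 47 of 82 bound, and 10.1 without replicate 2, with 60 of 77 bound. Both values passed. They were not tested against each other, so whether the size of the difference depends on the library stays open. With all protein-coding genes as the background the odds ratio was 12.8. Against that wider background 7 lists passed: those of the cytosolic ribosome, stress response, unfolded protein response, aminoacyl-tRNA synthetases, glycolysis and chromatin factors were bound more often, and odorant and gustatory receptors less often.

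Some known ATF4 targets and regulators of the stress response carried strong peaks, but the list as a whole did not pass. Of 20 genes, all with a candidate, 8 were bound (40%; odds ratio 1.98, 95% interval 0.699 to 5.27; Fisher's exact test p = 0.130, adjusted 0.518). They were Atf3, a bZIP factor gene (535.7, rank 28); Sesn, the sestrin gene (489.4); AsnS, asparagine synthetase (261.1); Nelf-E (254.0); Irbp18, which encodes a C/EBP-like partner of Crc (219.9); Thor, the 4E-BP translation inhibitor gene (107.7); eIF2beta (84.4); and scyl (64.2). The Nelf-E peak also lies within 500 bp of a start of RpL14, so it counts for the ribosomal list as well. The eIF2beta peak was weak in replicate 1, where it had a signal of 11.4 and ranked 23995. The unbound genes included crc and the kinase genes PEK (47.3) and Gcn2 (33.0), as well as eIF2alpha (22.0). Without replicate 2, using the strongest candidates of replicate 1 alone, the list passed, with 9 of 14 bound, an odds ratio of 5.01 and an adjusted exact p of 0.0430. The rest of the 20 genes had no candidate near a start in replicate 1 and left that comparison. The number of bound genes itself was 9 there and 8 in the optimal list. From the strongest candidates of replicate 2 alone it did not pass, with 7 of 20 bound and an odds ratio of 1.89. With all protein-coding genes as the background it passed, with an odds ratio of 5.16 and an adjusted exact p of 0.00684. At limits of 200 bp and 1 kb it did not, with odds ratios of 1.35 and 2.06 (adjusted exact p = 0.984 and 0.395). Nor did it with peaks given to the nearest gene (2.17, adjusted exact p = 0.549) or in the stronger optimal peaks (2.65, 0.288).

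Aminoacyl-tRNA synthetase genes, whose products charge tRNAs with amino acids, were bound in 8 of 13 cases, led by SerRS (192.9), IleRS (148.8), ArgRS (127.6) and GluProRS (96.96). Their odds ratio was 4.75 (95% interval 1.37 to 18.5; exact p = 0.00601), which did not pass after adjustment (0.0781); against all protein-coding genes it was 5.16 and passed (adjusted exact p = 0.00684). With 7 of 15 bound in each case, it was 3.07 without replicate 1 and 2.43 without replicate 2 (adjusted exact p = 0.213 and 0.439). None of the 14 redox defence genes with a candidate was bound, among them GstD1 (63.6), Gclm (60.001) and GstE1 (25.2) (odds ratio 0, 95% interval 0 to 0.890; exact p = 0.0278, adjusted 0.241). The direction turned when each peak went to its nearest gene at any distance, which gave 4 of 15 bound and an odds ratio of 1.32 (adjusted exact p = 0.938). The absence of bound genes also depended on the pooled list, with 2 of 14 bound without replicate 1 and 3 of 12 without replicate 2 (odds ratios 0.582 and 0.924, adjusted exact p = 0.948 and 1). GstD1 missed the lowest optimal signal of 63.98 narrowly. GstE13, a glutathione S-transferase gene outside the list, was bound with a signal of 552.5.

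Folding, metabolic and stress genes held single strong peaks without passing as lists against other genes with a candidate. With all protein-coding genes as the background, the unfolded protein response and glycolysis lists did pass. Unfolded protein response genes were bound in 7 of 17 cases, with Hrd3 (251.3), Herp (204.5), Sec61alpha (170.1) and Ire1 (123.5) strongest, whereas Hsc70-3 (30.3) and Gp93 (62.9) were not bound (adjusted exact p = 0.518). In amino acid and one-carbon synthesis 4 of 17 were bound, namely aay (263.8), AsnS, P5cr (100.5) and pug (80.6), and 2 of 8 amino acid transporter genes, gb (95.6) and CD98hc (72.9) (adjusted exact p = 1 for each list). Glycolysis had 5 of 11, led by Gapdh2 (377.6), Hex-A (257.2) and Pgk (170.4), and heat shock also 5 of 11, led by Hsp83 (266.3), Hsp27 (236.6) and Hsp26 (175.8) (adjusted exact p = 0.518 for each). Initiation factors had 8 of 27, with eIF6 (348.1) and eIF1 (209.5, a peak shared with RpL28), and autophagy 4 of 14, with Atg2 (107.6) and Atg17 (104.4) (adjusted exact p = 0.854 and 0.943). Replicate 2 had no candidate summit within 100 bp of the Atg17 summit. Proteasome genes had 2 of 20, Rpn5 (155.4) and Rpn3 (94.0), and ecdysis genes 2 of 10, Eip75B (270.8) and usp (93.4) (adjusted exact p = 0.528 and 1).

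Of 26 embryonic patterning genes, 7 had a candidate and none was bound; hb had a failed candidate of 57.3, and eve, ftz and Kr had none near a start (adjusted exact p = 0.528). Genes of chromatin and promoter factors were bound in 5 of 10 cases, Chro, Dref (157.2), Cp190 (134.0), Trl (130.2) and BEAF-32 (85.7) (adjusted exact p = 0.518). The cell type lists each had 6 or fewer genes with a candidate, and none passed (adjusted exact p from 0.577 to 1): elav (298.8) was bound among 4 neuron genes, moody (298.6) among 3 glia genes, sls (88.5) and Mef2 (67.3) among 6 muscle genes, ush (68.9) as the only haemocyte gene, fkh (185.5) among 2 gut genes, and Lpin (222.0) and FASN1 (73.2) among 4 fat body genes. No trachea gene of 3 and no germ line gene of 6 was bound. Odorant and gustatory receptor genes, a control list of 119, had 4 with a candidate and 0 bound, and the control list of 13 eggshell genes also had 4 and 0 (adjusted exact p = 0.835 for each).

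**Figure D4:**
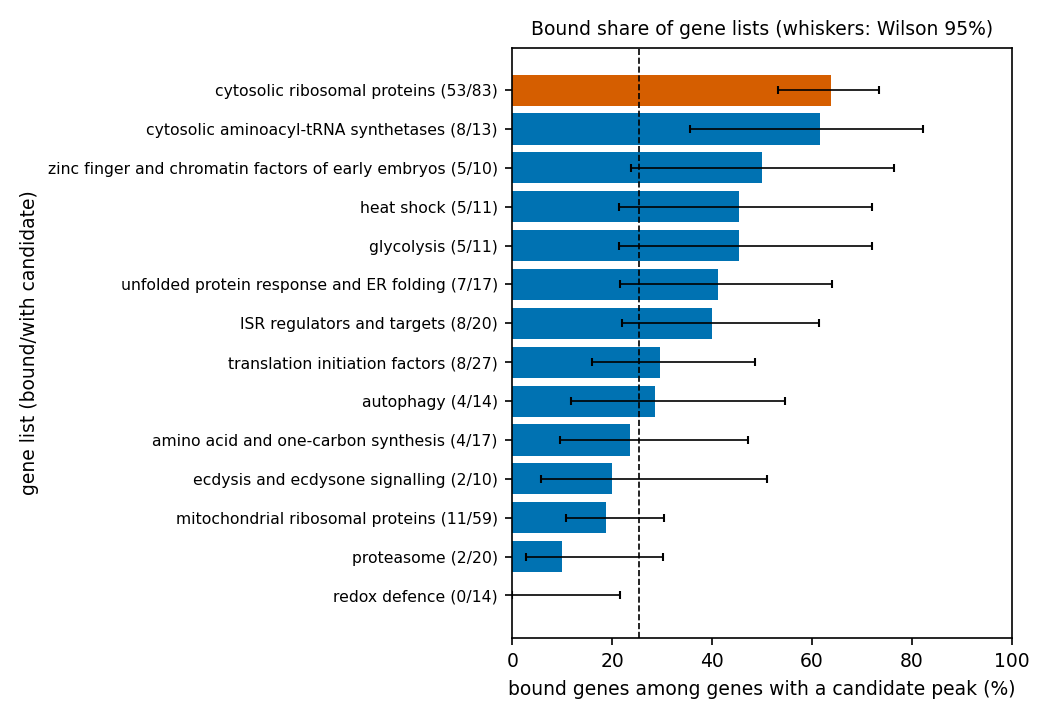
Share of bound genes among genes with a candidate peak, in percent, for the lists with at least 10 such genes; whiskers are Wilson 95% intervals, the orange bar passed the adjusted threshold and the dashed line marks the 25.3% of all genes with a candidate. Cytosolic ribosomal protein genes stand at 63.9% and redox defence genes at 0.

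The ATF4 recognition element was not more frequent at the summits than beside them. The C/EBP-ATF response element (CARE, TGATGNAAY) occurred within 100 bp of 32 of 2420 summits (1.32%, Wilson 95% interval 0.938 to 1.86) and in 32 flanking windows 1 kb away, with 31 pairs having it only at the summit and 31 only at the flank (exact McNemar test, two-sided, p = 1). The strict form TGATGCAAT occurred at 8 summits and 7 flanks, and the reversed CARE, a control of the same composition, at 23 and 24. None of the 25 strongest peaks had a CARE. The strongest with one were at CG1635 (338.4), Tina-1 (241.0) and an intron near bmm (216.0), and the strict form marked the promoter shared by RpL13 and Dref (157.2), a peak at Ptp99A (90.5) and the promoter of eIF2beta. Peaks with a CARE had a median signal of 84.3 against 97.3 for the others, a difference of -13.0 (permutation test, two-sided, 100000 resamples, p = 0.179). On simulated data, an element added to 1% of the summit windows was called in 75% of 200 simulations, and one added to 2% in 100%.

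Core promoter elements did stand out at the summits. The DNA replication-related element (DRE, TATCGATA), bound by Dref, marked 86 summits (3.55%) and 20 flanks (0.826%), with 85 pairs against 19 (exact McNemar p = 3.79e-11, adjusted 4.16e-10 over 11 elements). Motif 1 (GGTCACACT), bound by M1BP, marked 35 and 8 (exact p = 4.19e-05, adjusted 2.31e-04). Peaks with a DRE were led by Shc (467.4), Alg3 (364.3) and CG11151 (341.0), and those with Motif 1 by RpL7, a site near slp2 (218.3) and RpLP0 (212.0). Against failed candidates matched for GC content and promoter position, a comparison chosen after the data were seen, DRE was at 86 and 83 summits and Motif 1 at 35 and 42 (exact McNemar p = 0.876 and 0.489). The cyclic AMP element, AP-1, C/EBP, E-box, GAGA and Zelda elements did not pass, with the E-box at 58 summits and 80 flanks (exact p = 0.0651, adjusted 0.239) the nearest to the threshold.

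**Figure D5:**
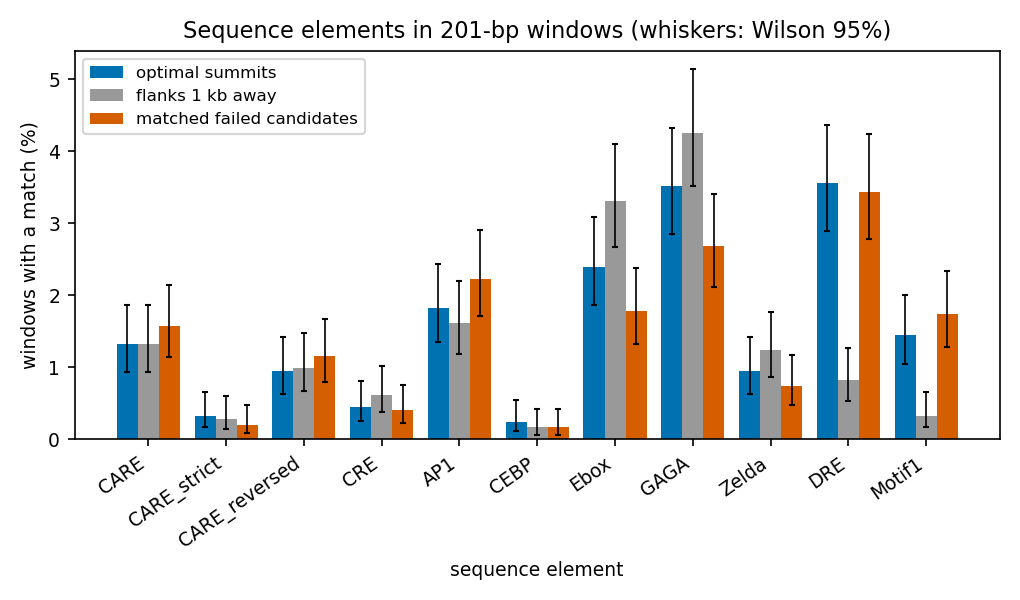
Share of windows reaching 100 bp to each side with a match to each element, in percent, at the 2420 optimal summits (blue), at flanks 1 kb away (grey) and at failed candidates matched for GC content and promoter position (orange), with Wilson 95% intervals. CARE stands at 1.32% at summits and flanks and at 1.57% at matched failed candidates. DRE stands at 3.55% at summits, 0.826% at flanks and 3.43% at matched failed candidates.

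Among all 8192 7-mers, 760 were more frequent at the summits than at the flanks and 1248 less frequent (exact McNemar tests, Benjamini-Hochberg adjusted p under 0.05). The most significant were AT-rich: AAAATAT occurred at 25.9% of the summits and 12.4% of the flanks (exact p = 9.06e-34, adjusted 7.42e-30), and TTAAAAA at 23.8% and 11.0%. GC-rich 7-mers such as CGAGGAG, at 0.413% and 4.01%, were less frequent. The GC content of the windows was 36.7% at summits, 43.0% at flanks and 41.7% at failed candidates. Some 7-mers with more G and C were also higher at the summits, among them CAGTGTA (7.73% against 1.49%), ACAGTGG (8.80% against 2.60%) and CACTGTA (6.69% against 1.98%). Against matched failed candidates, 21 remained higher at the summits, and 20 of these were among the 760; ACAGTGG was then at 8.80% against 3.88% (exact McNemar p = 1.57e-12, adjusted 1.29e-08).

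Small RNA genes did not gather peaks. Of the optimal summits, 11 lay within 500 bp of a tRNA gene (0.455%), against 74 failed candidates (0.337%; odds ratio 1.35, Fisher's exact test p = 0.361, adjusted 1 over 4 classes). The strongest were at CG8036 (325.3), RpL17 (146.0) and Sema1a (130.0). Optimal summits near snRNA genes numbered 1 against 13 failed ones, and near snoRNA genes 6 against 55, and neither class passed (exact p = 1 for each). Near rRNA genes there were 0 optimal and 0 failed summits, so that class could not be tested.

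The authors also deposited the lists on the older dm3 build. There the optimal list had 2257 peaks, 0.933 of the dm6 number, with a median signal of 100.6 against 96.9. The candidate lists were shorter in dm3, with 22762 against 30000 for replicate 1, 28637 against 30000 for replicate 2 and 20503 against 24369 for the pooled reads. Both dm6 replicate lists end at exactly 30000 regions. The strongest peak had a signal of 1273.65 in dm3 and 1273.8 in dm6.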

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

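The matched failed candidates, the CARE with 1 mismatch and the 300 strongest peaks were chosen only after the data were seen. Of 97 recomputed values, 81 stayed on their side of the threshold without turning from one direction to the other, or within the limits set for a value or count, and 1 reversed: the odds ratio of redox defence genes, 0 in the report, was 1.32 with peaks given to the nearest gene, and neither value passed after adjustment. The Pearson correlation of log2 signals was 0.764. Of the chromosome arms, 4 passed against arm length, 0 in the 1210 strongest peaks and 1 to 2 without a replicate. The ratio of X was 1.11 in the strongest peaks and 1.07 to 1.13 without a replicate, and that of 2R was 0.944 against arm length and 0.849 in the strongest peaks, where fewer peaks were tested. Sequences higher at summits numbered 456 as 6-mers, of which fewer exist, and 21 against matched failed candidates. Against all protein-coding genes 7 gene lists passed, and 1 to 2 without a replicate. For the other changes the cause was not tested. The replicate overlap ran from 52.9% to 74.2%, the promoter odds ratio from 2.58 to 8.11, and the CARE difference, 0 in the report, took both signs, from -1.33 to 0.0826 percentage points, never past the threshold. Read depth is unknown, and the 30000 regions per replicate limit what weak candidates can show. No comparison between groups, with samples paired or not, was possible because there is 1 group.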

Other observations

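The tests on matched failed candidates, with 1 mismatch allowed, on held-out chromosome arms and on DRE pairs away from starts, and the comparison of transposable elements, were chosen only after the main results were seen, as was the bound set on the CARE difference within 250 bp, although the choice of that window was not. Divergent promoters, where 2 genes start within 1 kb of each other and are transcribed apart, made up 42.2% of the 1224 optimal promoter peaks (516) and 30.9% of the 5562 failed promoter candidates (1721). That bound promoters favour divergent gene pairs was a hypothesis written down before this count, and the odds ratio was 1.63 (95% interval 1.43 to 1.85, Fisher's exact test p = 9.96e-14). The peak at CenG1A and mRpS23 (672.2) is an example in which 2 genes start close to a single summit. Annotated transposable elements held 6 optimal summits (0.248%) against 147 failed ones (0.670%; odds ratio 0.369, exact p = 0.00938).

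A family of related 7-mers (ACAGTGG, CACAGTG, CACTGTA, ACTGTGC) stayed more frequent at summits after matching for GC content and promoter position. To test chance selection, 10 sequences were chosen on the 754 matched pairs with both members on arms 2L, 2R and X and counted in the 507 pairs with both on 3L, 3R and 4, other pairs being left out. Of these 507 optimal summits 30.8% held at least 1 of them, against 18.3% of their matched failed candidates, with 125 pairs against 62, odds of 2.02 (95% interval 1.48 to 2.78, exact McNemar p = 4.76e-06). Chance selection alone is argued against by that interval, and which protein, if any, reads these sequences was not tested.

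For the absence of a CARE excess, base composition hiding the element was tested against matched failed candidates. The difference in share was -0.248 percentage points (95% interval -0.909 to 0.413), where the bound written before that test was 2. This argues against an excess of 2 points or more over weaker peaks of like GC content. Those candidates come from the same precipitation and may hold the element too, so an excess over unbound DNA of like GC content stays open. With 1 mismatch allowed, the shares were 29.1% at optimal peaks and 29.8% at matched failed candidates. Their ratio was 0.979 (95% interval 0.900 to 1.07), below the bound of 1.2. A consensus that is too strict is argued against by this only for an excess over those weaker peaks. A CARE elsewhere in the peak is argued against too, for an excess of 2 percentage points or more: within 250 bp of the summit, which spans a peak of 400 bp, the share was 3.22% against 3.60% in flanks, a difference of -0.372 points (95% interval -1.36 to 0.661, exact McNemar p = 0.523). Summits misplaced in the list as a whole stay open only in part: DRE matches were 2.12 times as dense within 50 bp of a summit as 150 to 250 bp away, an interval of 1.43 to 3.13 that excludes 1 but does not clear the bound of 1.5 written before. Signal that does not depend on Crc cannot be told apart from binding, because 0 libraries without the tagged protein were analysed here, and no biological explanation was tested.

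The DRE excess over flanks was weighed against the position and the base composition of the peaks. Against failed candidates matched for GC content and promoter position, the odds were 1.04 (95% interval 0.755 to 1.42, exact McNemar p = 0.876). Those against flanks were 4.47 (2.70 to 7.79). The DRE was thus about as frequent at weaker peaks of like GC content and position. Those candidates come from the same precipitation and may be bound too. The comparison therefore cannot tell whether GC content or position, which the matching does not separate, accounts for the excess over flanks. Among the 983 pairs with summit and flank both over 500 bp from any start, 0 had a DRE only at the summit and 6 only at the flank, odds of 0 (95% interval 0 to 0.849, exact p = 0.0313). The excess over flanks was therefore confined to pairs with a summit or flank within 500 bp of a start. Away from starts, promoter position alone predicts equal shares and not a deficit, so how far it accounts for the excess stays open. No biological explanation was tested.

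The binding of cytosolic ribosomal protein genes was weighed against their high transcription and their promoter elements. Among genes with no exact DRE or Motif 1 match within 200 bp of a start, 31 of 50 ribosomal protein genes were bound. The odds ratio was 4.87 (95% interval 2.66 to 9.16, Fisher's exact test p = 4.53e-08). Exact matches to these elements alone therefore do not account for the binding. Variant forms of the elements were not scored, so their part stays open. Of 44 genes outside the ribosome listed as abundantly transcribed from general knowledge, 40 had a candidate and 16 were bound, an odds ratio of 1.98 (0.981 to 3.90, exact p = 0.0429). That interval reaches 1 on one side and the 3.35 lower bound of the ribosomal genes on the other, so high transcription stays open. No biological explanation was tested.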
